A study of Mus musculus with 8 samples.

How the data were processed

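Total RNA was extracted from frozen livers with Trizol, and 100 ng per sample was ligated to a Cy3-labelled nucleotide and hybridised to Agilent mouse miRNA arrays, per the labels' protocols. Each of the 8 arrays carried 1 sample, and the series states that 4 animals were taken per strain, so replicates are separate animals. Samples were grouped by the genotype in their labels, db/+ or db/db, which is called strain in this text. Replicate numbers 3 and 4 come from the titles; the other db/+ numbers only name the arrays.

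The spot intensity values came from scanner files made with Agilent Feature Extraction 9.5.3.1, per the file headers, while the series text names version 9.3.5; scans used extended range settings of 100 and 5%, per the labels. Processed spot intensity had been background-subtracted but not scaled between arrays, per the file headers, and can lie below 0. The flags for detected miRNAs, spots well above background, saturated spots and outlier spots are 0 or 1, of another kind than intensity, per the file headers. The deposited table of the whole series held the raw median intensity of each spot, equal to the scanner files in all 12493 rows of each array, with medians of 95.5 to 148 per array. The authors also deposited a score per miRNA for 139 miRNAs, which the series describes as global median normalized and log transformed. Set against the scanner files, the most common line through these scores had the slope of a logarithm of base close to 20 (19.97 to 20.03), with a constant per array and medians of 1.54 to 1.56. Most scores lay off that line by more than 0.002: on it were 14 of 99 miRNAs with a signal above 10 on db/+ replicate 4 and at most 62 of 139, on db/+ replicate 1. The scores were converted to log2 as of base 20, so their fold changes rest on that estimate. The base, and how the 139 miRNAs were chosen, are not given in the sources used here.

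Control spots and spots flagged as outliers (3.4% to 4.8% of the 11540 miRNA spots per array) were left out. No miRNA spot was saturated. Spots of a probe were averaged, then the probes of a miRNA, up to 4, on the linear scale. Each array was divided by its median over the miRNAs detected on all 8 arrays, relative to the geometric mean of the arrays, which gave factors from 0.21 to 5.63 in db/+ and from 0.85 to 1.06 in db/db. Scaled values were floored at 4.59, the median over arrays of the lowest signal of a detected miRNA, before log2 was taken. A miRNA was tested when it was detected on all 4 arrays of at least 1 strain. The floor can understate fold changes of dim miRNAs. It can also overstate them, since on db/+ replicates 2 and 4 the lowest detected scaled signals, 13.1 and 25.9, lay above it. Values between the floor and those signals were not reliably measured there. Floored values of a miRNA are equal, which can narrow the spread used by the test.

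Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, strain as the only term, two-sided) with Benjamini-Hochberg adjustment over the 127 miRNAs. SAM was computed with its fudge factor over all 70 label permutations at a false discovery rate under 5%. 21 miRNA lists were fixed beforehand, and the 11 with at least 3 tested members were put to camera and fry in limma. Array values were compared with exact permutation tests, except that for the deviation from the strain's median the medians were held fixed. Values were read with the data.table package, version 1.17.8, and plots drawn with matplotlib 3.10.9. A miRNA not well above background on every array of a strain has only a bound there, computed against the lowest scaled signal among miRNAs well above background or its own signal where that was higher.

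Named were all miRNAs past the threshold (up to 30), filled to 20 by smallest p, then up to 4 tested members per list by smallest p, then miR-122, miR-29a, miR-29b, miR-29c, miR-34a and miR-22, and any miRNA detected on all arrays of 1 strain and none of the other. The array's names are those of its design and can be old. Coordinates are those of the array files, whose headers name mm9. Enclosing genes come from RefSeq gene records of assembly GRCm38.p6, used for names only, without regard to strand. For miRNAs with several gene copies no enclosing gene was assigned. Signal of close relatives (miR-103 and miR-107, the let-7 members, the miR-29 members, miR-125a-5p and miR-125b-5p) may be shared between probes.

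The procedure was tested on simulated values for 127 miRNAs, 4 arrays per strain and 30 changed miRNAs in each of 100 runs. limma recovered 34.9% of changes of 0.5 on the log2 scale, 79.6% of changes of 1 and 98.0% of changes of 2, and SAM 27.8%, 81.9% and 99.4%. False calls made up 3.67% of limma's calls and 5.38% of SAM's, and 9 of 100 runs without any change gave a limma call. Changes near 0.5 were thus often missed in the simulation, and the number of arrays limits the precision of every value. The simulated noise was normal, independent between miRNAs and equal in SD for both strains. It held no array effects, and scaling, floor and filter were not repeated. The real db/+ arrays ranged 26.8-fold in signal, against 1.26-fold in db/db, so these rates may not hold for them.

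Alternatives were fixed before the data were examined: the summary signal of the extraction software, log2 means of probes, normexp background correction with an offset of 50, other scaling (75th percentile, quantile, none), stricter and no detection filters, another detection flag, a lower floor, outlier spots kept, SAM, an intensity trend, array weights, the authors' deposited scores, the raw intensities, the replicate number as a block, and each array left out. Added after the data were seen were the omission of db/+ replicates 1 and 4 together, slide column as a block, cyclic loess, the scaling factor as a covariate and a higher floor. Slide and scan as blocks were not fitted because all arrays shared 1 slide and 1 scan.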

Results

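The series compared the livers of 4 db/db mice with those of 4 db/+ mice to find microRNAs (miRNAs) whose level differs in the diabetic animals. The db/db mouse lacks a working leptin receptor and becomes obese and diabetic, and the heterozygous db/+ mouse served as the control. miRNAs are short RNAs that bind messenger RNAs and lower their translation or stability. Total RNA of each liver, 100 ng, was labelled with Cy3 and hybridised to a 1-colour array with probes for 567 mouse miRNAs and 10 miRNAs of a mouse herpesvirus, 1 array per animal. A miRNA is given here by the name in the array files, and its level as scaled signal on a log2 scale, mean ± SD over 4 arrays.

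Of the 567 mouse miRNAs, 303 were detected on no array and 89 were detected on all 8 arrays. The db/+ arrays detected 255, 127, 169 and 91 mouse miRNAs (160.5 ± 70.6, SD, n = 4) and the db/db arrays 136, 133, 166 and 145 (145 ± 14.9, SD, n = 4). The difference in means, db/db minus db/+, was -15.5 (two-sided exact permutation p = 0.8); it was 16 without db/+ replicate 1, -26.7 without db/+ replicate 2 and -38.7 without db/+ replicate 4. The liver-specific miR-122 was detected on every array, at 15.38 ± 0.70 in db/+ and 15.48 ± 0.06 in db/db. Signal before scaling ranged 26.8-fold among the db/+ arrays and 1.26-fold among the db/db arrays. Its mean on the log2 scale differed by -0.037 (two-sided exact permutation p = 0.971). That difference near 0 came from a bright and a dim db/+ array that offset each other: it was 0.79 without db/+ replicate 1, -0.79 without db/+ replicate 4, and -0.32 and 0.18 without db/+ replicates 2 and 3. The deviation from the strain's median was smaller in db/db by a mean difference of -1.45 (permutation p = 0.0286, the smallest that 4 against 4 arrays allow). The medians were not recomputed for each permutation, so this p is not exact, and this last test was chosen after the values were seen. All 8 arrays lay on 1 slide, with the db/db arrays in row 1 and the db/+ arrays in row 2, so slide row and strain cannot be told apart.

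**Figure D1:**
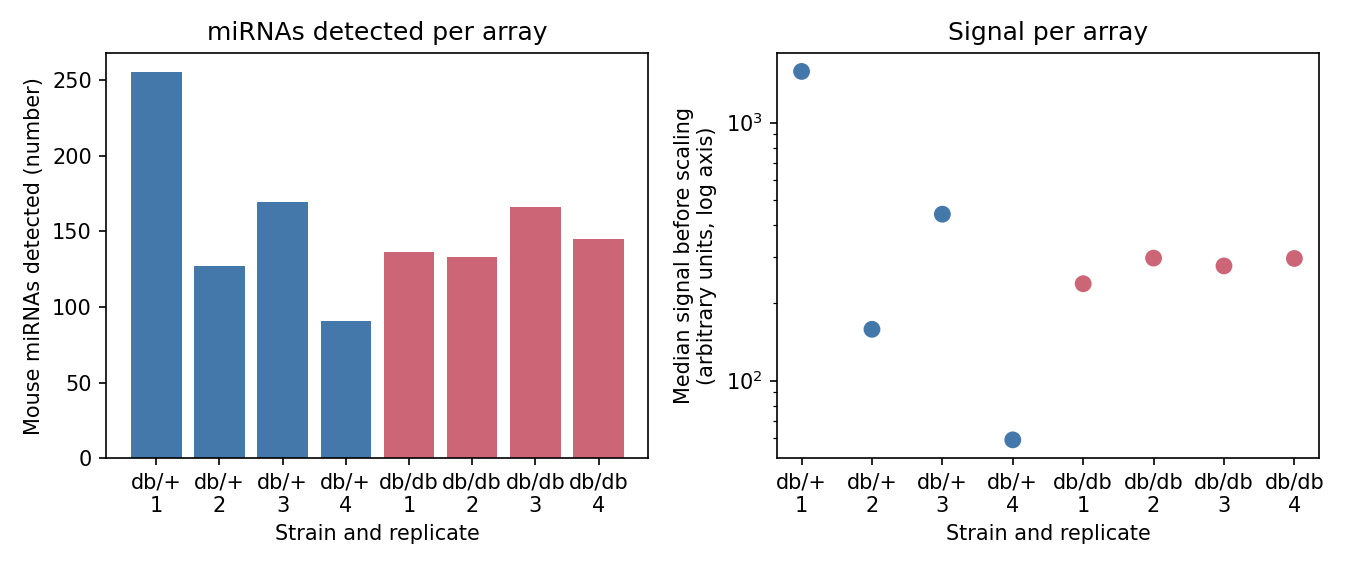
Left, the number of mouse miRNAs detected on each array; right, the median signal of the miRNAs detected on all arrays, before scaling, in arbitrary units on a log axis. Each bar or point is 1 array, blue for db/+ and red for db/db, and the db/+ arrays spread from 59.0 to 1578 in signal while the db/db arrays lie between 237 and 298.

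In the db/db livers 12 miRNAs rose and 7 fell. miR-34a, a target of p53 that is known to repress the deacetylase Sirt1, rose 5.80-fold, from 7.14 ± 0.35 to 9.68 ± 0.49 (log2 fold change 2.54 ± 0.26, SE, n = 4 per strain; limma adjusted p = 1.7e-04). miR-31 and miR-378 rose 2.14-fold and 2.12-fold. miR-676, from a locus within the gene Eda on chromosome X, passed as higher by an amount that depended on the floor set for low values. Its direction also depended on the processing, with log2 fold changes of -0.48 under normexp and -0.23 with the raw median intensities. On the side of the decreases stood miR-125a-5p, let-7e and miR-99b, which are encoded next to one another on chromosome 17, miR-21, and the leukocyte miRNAs miR-142-3p and miR-223. The liver-specific miR-122 had a log2 fold change of 0.10 ± 0.30 (adjusted p = 0.874) and did not pass the test.

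The test was limma's moderated test over the 127 miRNAs detected on all 4 arrays of at least 1 strain, with Benjamini-Hochberg adjustment and a threshold of 0.05, and 19 miRNAs passed. All 127 were detected on all 4 db/db arrays, but only 89 of them on all 4 db/+ arrays, so the rule can favour increases among dim miRNAs. Over these 89 alone 14 passed, 8 higher and 6 lower. Without adjustment 33 of the 127 had a p under 0.05, against 6.35 expected by chance. For 29 of the 127 miRNAs the values of the strains did not overlap, where chance gives 2.86%. Among the 19, the strains did not overlap for 18, the exception being miR-705, and all 4 db/db arrays lay on the same side of the db/+ mean for each of the 19. SAM, the method named by the series, called 26 miRNAs at a false discovery rate under 5%, 18 higher and 8 lower, and these included all 19.

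**Figure D2:**
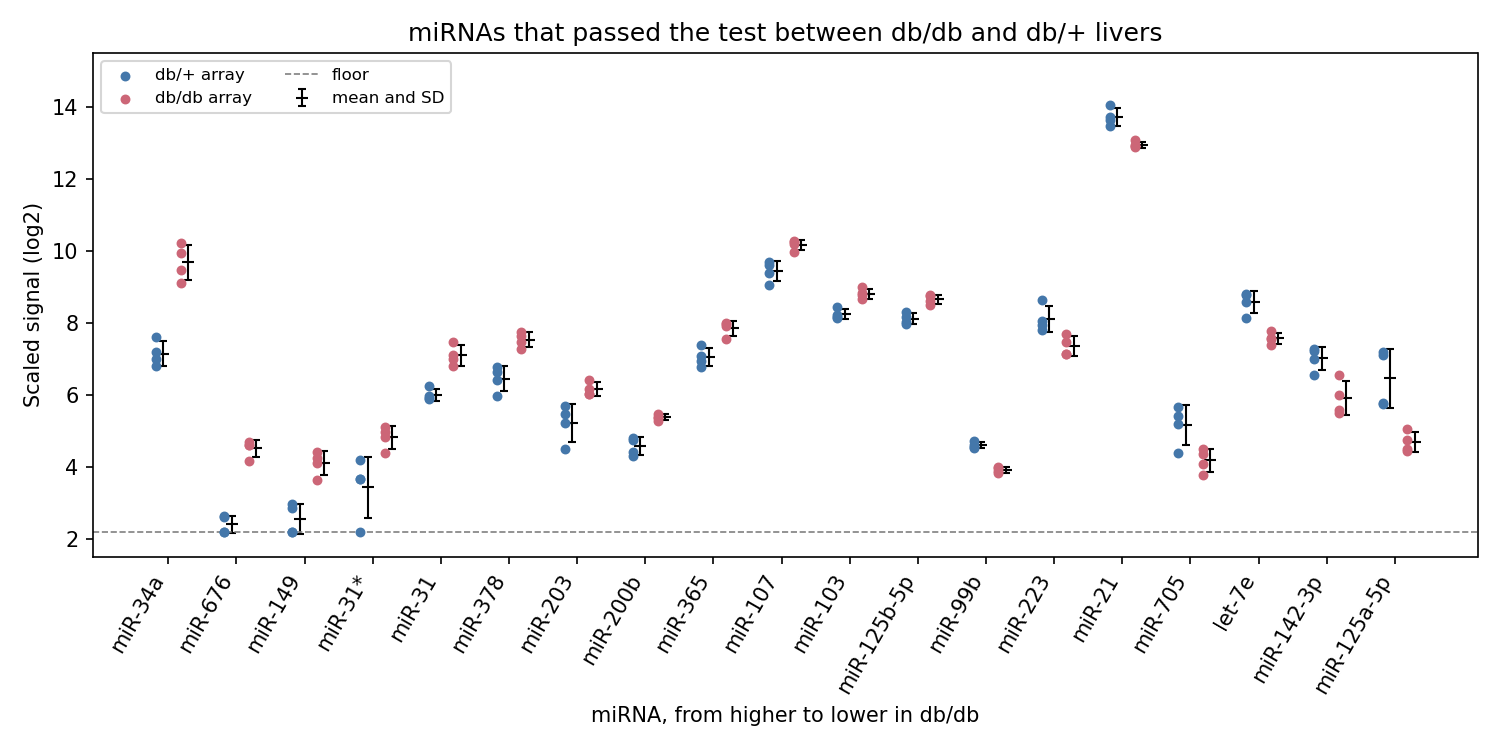
Scaled signal (log2) of the 19 miRNAs that passed the test, ordered from the highest to the lowest log2 fold change; points are single arrays (blue db/+, red db/db), black bars are mean and SD over 4 arrays, and the dashed line is the floor at 2.20. miR-34a stands at 7.14 in db/+ and 9.68 in db/db, and 2 db/+ arrays each of miR-676 and miR-149 lie on the floor.

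The rise of miR-34a was the most stable of these results. Its gene lies on chromosome 4 at 149442584 to 149442603 (mm9, as in the array files), outside the other genes of the RefSeq records. miR-676 (chromosome X, 97576493 to 97576510) was at 4.51 ± 0.24 in db/db and was detected on 2 of 4 db/+ arrays, the other 2 being set to the floor (adjusted p = 5.07e-05). It was not well above background throughout either strain. Its log2 fold change was thus not a measured size: it was 2.11 with this floor, 3.04 with a lower floor and 0 with a higher floor, chosen after the data were seen, under which all 8 values of miR-676 and of miR-149 lay. miR-149, within Gpc1 on chromosome 1 (94746963 to 94746980), was the 1 miRNA detected on all 4 arrays of one strain, db/db, and on none of the other (adjusted p = 0.0032). A detection flag at low signal does not by itself show presence, as a viral miRNA below shows. miR-149 was not well above background on any db/+ array and was so on 2 of the db/db arrays, but its difference had no firm lower bound. Set against the lowest signal well above background (or its own where higher), averaged over the db/+ arrays, the db/db mean of 4.10 was 1.39-fold higher, yet on db/+ replicates 2 and 4 that lowest signal, 4.81 and 5.20, lay above this mean.

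miR-31 (chromosome 4, 88556518 to 88556534) rose by a log2 fold change of 1.09 ± 0.17, to 7.09 ± 0.28 in db/db (adjusted p = 0.0032), and its star strand miR-31* rose by a log2 fold change of 1.39 ± 0.38 (adjusted p = 0.0317, with 1 db/+ array at the floor). The star strand was detected on 2 of the 4 db/+ arrays and had 0.20 (limma adjusted p = 0.208) with the higher floor, so its size is uncertain. miR-378, which lies within Ppargc1b, the gene of a coactivator of oxidative metabolism (chromosome 18, 61557492 to 61557505), rose from 6.44 ± 0.35 to 7.53 ± 0.21 (adjusted p = 0.0063). Its other arm, miR-378*, had a log2 fold change of 0.80 ± 0.28 and did not pass (adjusted p = 0.102). miR-107, within the pantothenate kinase gene Pank1, and miR-103, which differs from it by few bases, rose by log2 fold changes of 0.74 and 0.58 (adjusted p = 0.0164 and 0.0220). Probes for such close relatives can share signal, so the separate values of miR-103 and miR-107 are uncertain. The remaining increases were miR-203 (0.94), miR-200b (0.81), miR-365 (0.80) and miR-125b-5p (0.54), with limma adjusted p-values from 0.0079 to 0.0281. Without db/+ replicate 4 the log2 fold changes of miR-203 and miR-31* were 0.60 and 0.88.

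let-7e, miR-99b and miR-125a-5p fell together. Their mature sequences lie between 17967164 and 17967804 on chromosome 17, within Spaca6. miR-125a-5p went from 6.45 ± 0.81 to 4.68 ± 0.28 (3.41-fold, adjusted p = 0.0085), let-7e from 8.57 ± 0.31 to 7.57 ± 0.16 (2.00-fold, adjusted p = 0.0063) and miR-99b from 4.59 ± 0.08 to 3.91 ± 0.08 (1.60-fold, adjusted p = 0.0066). In db/+, miR-125a-5p was 5.77 and 5.73 on the brighter replicates 1 and 3, and 7.19 and 7.12 on the dimmer replicates 2 and 4. Its db/db values were 4.44 to 5.06. The size of its fall thus varied with the brightness of the db/+ arrays and is uncertain. The dim miR-99b was not detected on every array and was not well above background throughout either strain. With the authors' deposited log values it had -0.37 (limma adjusted p = 0.615). miR-21, which lies within Vmp1 and is known from proliferating and fibrotic tissue, fell from 13.73 ± 0.25 to 12.95 ± 0.09 (adjusted p = 0.0085). miR-142-3p and miR-223, which are made mainly in blood-forming cells, fell by 1.10 and 0.74 on the log2 scale (adjusted p = 0.0164 and 0.0434). miR-705 fell by 0.99 (adjusted p = 0.0366) and was not well above background on any db/db array, a 1.98-fold difference that is the ratio of the measured means. It was detected on all 4 db/+ arrays and well above background on 2 of them.

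The rule for naming also took miR-140*, the next by p-value, which did not pass (log2 fold change 0.48, adjusted p = 0.0543). Of the liver and diabetes miRNAs fixed for naming, miR-29a, miR-29b and miR-29c had log2 fold changes of -0.43 ± 0.20, -0.69 ± 0.31 and -0.51 ± 0.17 (adjusted p = 0.187, 0.185 and 0.086). Under quantile normalization miR-29a and miR-29c passed (adjusted p = 0.0068 and 0.0208), as they did under cyclic loess (0.0278 and 0.0183) and with log2 means of probes (0.0454 each); miR-29c also passed with the other detection flag, with array weights and without db/+ replicate 4, and miR-29b with array weights. Without db/+ replicate 4 miR-29b had -1.05 (adjusted p = 0.0503). miR-22 had 0.42 ± 0.23 (adjusted p = 0.265).

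The db/+ replicates 1 and 4, the brightest and the dimmest array, were left out as a check chosen after the data were seen: 9 miRNAs passed, 4 higher and 5 lower, and 8 of them were among the 19. Scaling to the 75th percentile gave 6 higher and 8 lower, cyclic loess 10 higher and 11 lower, and the mean of log2 probe values 6 higher and 9 lower, so the excess of increases over decreases depended on the processing. Without scaling 0 miRNAs passed, with normexp background correction 2 (miR-34a and miR-107), with the authors' deposited log values 3 and with the raw median intensities 1 (miR-34a), and weighting the arrays gave 42. With normexp the log2 fold changes of miR-676, miR-149, miR-200b, miR-203 and miR-31* turned negative. With any single array left out, 9 of the 19 kept their call: miR-34a, miR-676, miR-149, miR-31, miR-378, let-7e, miR-99b, miR-125a-5p and miR-21. Among these 9, miR-31 and miR-378 lost it with db/+ replicates 1 and 4 both left out. In that fit of fewer arrays each of the 19 kept a share of at least 0.607 of its log2 fold change. miR-21 had -0.29 (adjusted p = 0.283) under quantile normalization, and miR-99b had -0.0031 (adjusted p = 0.991) with the higher floor, which also ended the calls of miR-676 and miR-149. All but miR-34a also lost it with normexp, and all 9 did without scaling. miR-103, miR-203, miR-125b-5p, miR-31*, miR-705 and miR-223 lost theirs in 5 to 7 of the 8 fits that left out 1 array, and miR-200b, miR-365, miR-107 and miR-142-3p in 1 to 3.

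Groups of miRNAs were fixed before the data were examined. Among 12 tested miRNAs tied to insulin action and obesity, 4 rose (miR-34a, miR-200b, miR-107 and miR-103) and none fell, and adjusted over the list alone the same 4 rose and miR-29c fell. The median of this list was 0.43, and -0.20 with normexp. Among 4 tested leukocyte miRNAs, miR-142-3p and miR-223 fell, the same 2 adjusted over the list alone, while miR-342-3p had a log2 fold change of -0.54 ± 0.34 and miR-146a of -0.04 ± 0.20; all 4 were negative except for 1 under quantile normalization. Of the 9 tested hepatocyte-abundant miRNAs none passed, also adjusted over the list alone.

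As whole groups, none of the 11 lists with at least 3 tested members passed camera with its preset correlation of 0.01 after Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. These were the leukocyte list, lower (adjusted p = 0.0654, and adjusted p = 0.382 with an estimated correlation), and the miR-29 family, lower (adjusted p = 0.224, and adjusted p = 0.595 with an estimated correlation). With an estimated correlation 0 lists passed. fry, which asks whether the members move one way without comparing them with other miRNAs, gave 3 lists past the threshold: insulin action and obesity, higher (adjusted p = 0.0115), star strands, higher (adjusted p = 0.0115), and leukocyte, lower (adjusted p = 0.0290). None of these 3 passed fry under the 75th percentile (adjusted p = 0.222, 0.235 and 0.0585), without scaling (0.968 each) or without db/+ replicates 1 and 4 (0.571, 0.626 and 0.0738), nor without db/db replicate 2 alone (0.0543 each). Without db/+ replicate 4 alone the insulin and star lists did not pass (0.375 and 0.288), and the leukocyte list did not without db/+ replicate 1, db/+ replicate 2 or db/db replicate 3 (0.0638, 0.101 and 0.0922). Under quantile normalization the insulin list did not pass fry (adjusted p = 0.0999) and the miR-29 family, lower, did (0.0130). That family also passed fry over the miRNAs detected on all 8 arrays (0.0304) and without db/+ replicate 2 or db/+ replicate 4 (0.0149 and 0.0119). The stellate and smooth muscle list, higher, passed fry over the miRNAs detected on all 8 arrays (0.0177) and with the replicate block (0.0486). The insulin list did not pass over the miRNAs detected on all 8 arrays (0.0575), nor the leukocyte and star lists with no filter (0.150 and 0.483). The leukocyte list passed camera over the miRNAs detected on all 8 arrays (adjusted p = 0.0344, and adjusted p = 0.229 with an estimated correlation), and without db/+ replicates 1 and 4 it had an adjusted p of 0.292. Camera compares a list with the other tested miRNAs, whose median lay at 0.15, so its direction was lower for the hepatocyte-abundant list although that list's own median was 0.15. For the miR-30 family and for the clusters of miR-23, miR-27 and miR-24, the medians were -0.0028 and -0.019 and fry's direction was higher, with no call.

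The 8 tested miRNAs of lipid and cholesterol metabolism included 2 that rose, miR-34a and miR-378, and 1 that fell, miR-223; adjusted over the list alone 3 rose, with miR-378*, and 1 fell. In the let-7 family let-7e alone changed among 9 tested members, and the same held adjusted over the list alone. The other let-7 members had log2 fold changes from 0.0032 (let-7i) to 0.40 (let-7c), none past the test. A positive value was found for 8 of the 9 members, but for 6 under the 75th percentile and under cyclic loess, 4 under quantile normalization, and 7 without scaling and with normexp. All 9 tested star strands had a positive log2 fold change, median 0.26, of which miR-31* rose, and adjusted over the list alone miR-31* and miR-140* rose. Most of the 9 were detected on all 4 db/db arrays but not on all 4 db/+ arrays, so the rule for testing can favour positive values. Over the miRNAs detected on all 8 arrays too few star strands were left to test the list. The number with a positive value was 8 under the 75th percentile, 7 under cyclic loess, 8 without scaling and 1 under normexp.

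Markers of other cell types gave few calls. Among 7 tested miRNAs of stellate and smooth muscle cells miR-31 rose, and miR-214 and miR-143 had log2 fold changes of 0.64 and 0.33 that did not pass. The endothelial miR-126-3p and miR-126-5p had 0.10 and 0.28, the erythroid miR-451 0.45 and the pancreatic miR-7a 0.36, none past the test. Of the epithelial miRNAs found in bile ducts, miR-200b rose and miR-200a had 0.64 ± 0.32 (adjusted p = 0.228). Of the muscle list, 0 of 7 miRNAs were detected on any array, and 3 of 9 neural miRNAs were detected on some array but none was tested. Among miRNAs of proliferation miR-21 fell and miR-221 had 0.31. The miR-34 family had 1 tested member of 5, miR-34a. Counts adjusted over the list alone were the same for the lists of this paragraph and for the miR-29 family, of which 0 of 4 tested members passed. The miR-30 family (5 tested), the miR-17 cluster and its paralogs (8 tested), those of miR-23, miR-27 and miR-24 (5 tested) and the imprinted Dlk1-Dio3 cluster (2 tested of 52 on the array) had no member past the test.

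**Figure D3:**
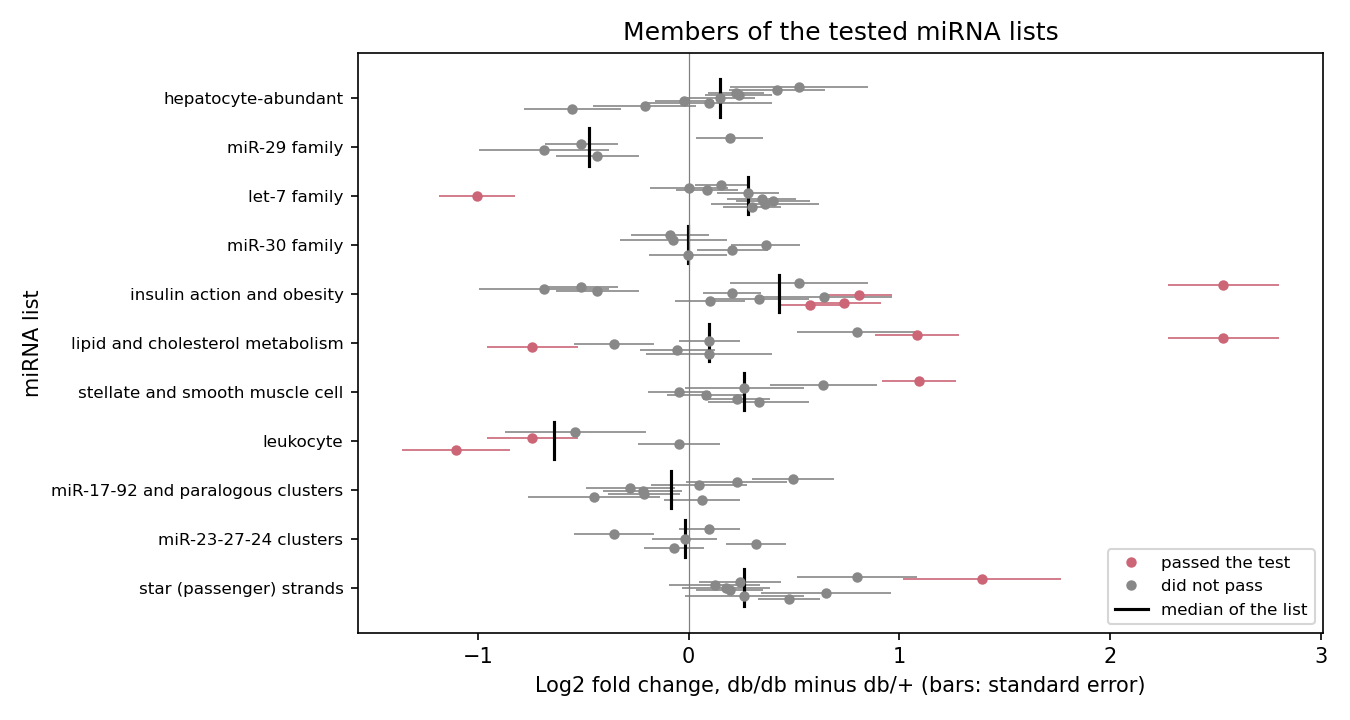
Log2 fold change (db/db minus db/+) of the tested members of the 11 lists put to the group test; points are miRNAs, horizontal bars their standard errors, red points passed the test over all 127 miRNAs and black lines are list medians. The leukocyte list has a median of -0.64 with 2 of 4 members past the test, and let-7e lies at -1.003, apart from the other let-7 members.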

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

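The test of the slide row, and the fits with the scaling factor as a covariate or without db/+ replicates 1 and 4, were chosen after the data were seen.

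Over 126 groups of 4 values examined for an array standing apart, 6 were found, where chance gives 6.3. In db/+, miR-29c was 11.20 on replicate 2 against 10.60 to 10.64 on the other arrays. On db/+ replicate 4, miR-93 was 5.46 against 6.14 to 6.20, miR-19a was 4.71 against 5.67 to 5.83, and the negative-control signal was 123.7 against 79.4 to 84.6. In db/db, miR-22 was 12.47 on replicate 2 against 12.41 to 12.42, and miR-146a was 5.59 on replicate 4 against 5.13 to 5.17. Outside the tested miRNAs, the viral mghv-miR-M1-1 was detected on db/db replicate 1 at a scaled signal of 8.33, above the db/+ arrays, whose highest was 4.39.

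Of the 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, gave as many miRNAs. It gave 19 with limma (highest other 3) and 26 with SAM (highest other 14). That argues against grouping by chance for both counts, but 1 of 35 is the smallest share that 4 against 4 arrays allow. Chance is thus not excluded, and the real split is also the split by slide row. For the lists the real split gave 0 and the others up to 2; all 35 give at least 0 by construction, so this count says nothing about chance.

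The calls stand beside a wide range of signal among the db/+ arrays. With signal level on the log scale as a covariate the 19 miRNAs kept a median share of 1.003 of their log2 fold change, but the strain means of that level differed by only -0.037, so the fit could not have moved the fold changes and decides nothing about signal level. Without db/+ replicates 1 and 4 they kept a median share of 0.917, with a lower quartile of 0.832 and a lowest of 0.607. The differences as a set thus did not rest on these 2 arrays alone. However, the 19 were chosen with both arrays included, which favours a high share. Since a bright and a dim array were left out together, the check decides nothing about signal level either. Slide row cannot be told apart from strain, since 0 of the 2 rows hold both, and the strain itself stays the untested biological explanation.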

How the results depend on the processing

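Between 1 and 42 miRNAs passed where any did, against 19, and the cause was not tested unless stated. The count was 2 with normexp, 0 without scaling (the arrays then differ in signal by their scaling factors), 4 with no filter (567 miRNAs tested; 3 of the 4 among the 19), 42 with array weights (all 19 included), 3 with the authors' deposited log values (2 shared, miR-34a and let-7e; 18 of the 19 are in those values, all with the same sign) and 1 with the raw median intensities. After the data were seen, omission of db/+ replicates 1 and 4 gave 9 (fewer arrays; 8 shared) and a floor at the highest of the arrays' lowest detected signals 12 (11 shared). Leaving out each array gave 11 to 20, with 11 without db/db replicate 2 and 12 without db/db replicate 3. Other settings gave 13 to 26, among them 17 with slide column as a block, where miR-103 and miR-125b-5p lost their calls. The split into higher and lower was 12 and 7, and moved to 6 and 8 with the 75th percentile, 6 and 9 with log2 means of probes, 10 and 11 with cyclic loess, 8 and 8 with the other detection flag and 6 and 8 without db/+ replicate 4. The median log2 fold change of all tested miRNAs, 0.15, was 0.024 with the 75th percentile, 0.012 without db/+ replicate 4, -0.087 with the raw table and -0.18 with normexp. Taken miRNA by miRNA, the median shift was -0.126 with the 75th percentile and -0.128 with normexp.

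SAM called 26, 11 with the deposited values (10 higher, 1 lower), 38 with a fudge factor of 0, 28 without db/+ replicates 1 and 4 (11 higher, 17 lower) and 17 to 36 with each array left out (17 without db/db replicate 4). Lists past the threshold numbered 0, 3 with fry, 1 with miRNAs detected on all 8 arrays, 1 with no filter and 0 to 1 with each array left out (the leukocyte list without db/+ replicate 2, db/db replicate 1 or db/db replicate 4). As for pairing, the titles share replicate numbers 3 and 4 between strains, and these arrays also share a slide column. They correlated at 0.036 and 0.307, so the numbers were not taken to pair animals. The replicate block, which kept only numbers 3 and 4 apart, gave 18 miRNAs, all among the 19 (miR-125b-5p lost its call), and 1 list, leukocyte. With an estimated correlation the leukocyte list had an adjusted p of 0.229 over miRNAs detected on all 8 arrays, 0.175 with no filter, 0.423, 0.351 and 0.349 without those 3 arrays, and 0.457 with the replicate block, and so passed in none of them.

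miR-34a passed in 28 of 29 settings. Log2 fold changes turned negative with normexp for miR-676 (-0.48), miR-149 (-0.57), miR-200b (-0.31), miR-203 (-0.028) and miR-31* (-0.45), and with the raw table for miR-676 (-0.23), miR-149 (-0.31), miR-200b (-0.090) and miR-31* (-0.18). These values are dim, normexp adds an offset of 50, and the raw table holds no background subtraction. Over 1764 values, 78 differed in sign from the main setting, 9 of them of called miRNAs. The 1764 hold named miRNAs, with the main setting's own values included, and array-level values (number detected and overall signal). The highest adjusted p with an array left out was 0.0386 among the 9 calls kept in all such fits (miR-31 without db/+ replicate 4), and 0.245 among the rest (miR-125b-5p without db/+ replicate 4). Scaling to the median of all miRNAs was not run, since that median was not above 0 on every array. The dim arrays limit dim miRNAs: db/+ replicate 4 detected 91.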

Other observations

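The tests on relatives in sequence, the omission of db/+ replicates 1 and 4, and the further shuffles of neighbours were chosen after the data were seen, as was the exclusion of neighbours that are arms of one hairpin.

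Detection outside the tested miRNAs lay mostly on 1 array. Of 264 mouse miRNAs detected on some array, 137 did not meet the rule for testing. Of the 264, 91 were detected on db/+ arrays alone and 5 on db/db arrays alone, 1 of which, miR-149, was tested. Of the 77 found on a single db/+ array and no db/db array, 73 were on db/+ replicate 1, the brightest. Of the imprinted Dlk1-Dio3 cluster 20 of 52 miRNAs were detected on some array and 2 were tested, miR-487b (log2 fold change -0.13 ± 0.33) and miR-494 (0.16 ± 0.55). Of the 10 viral miRNAs 4 were detected somewhere. mghv-miR-M1-8 had a signal of 436 on db/+ replicate 1 and of 25.4 on db/db replicate 3 and was detected on no other array. mghv-miR-M1-2, not expected in mouse liver, was flagged as detected on db/+ replicates 1, 2 and 3 and db/db replicates 2 and 3. Its signal was 11.5 to 30.7 over all arrays, so a flag at such low signal does not by itself show that a miRNA was present. The same caution holds for the flags of dim miRNAs that passed the test, such as miR-149, miR-676 and miR-99b.

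SAM alone called 7 further miRNAs, 6 higher and 1 lower, with limma adjusted p-values from 0.0543 to 0.152. They were miR-140*, miR-378*, miR-93, miR-214, miR-324-5p, miR-340-3p and, lower, miR-362-3p; miR-324-5p, miR-340-3p and miR-362-3p are named after their values were seen.

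miR-99b, let-7e and miR-125a-5p, neighbours on chromosome 17, fell together. The other arm of the miR-125a hairpin, miR-125a-3p, named after its value was seen, had a log2 fold change of -0.44 and did not pass. Cross-hybridisation from relatives would need these to fall too, yet 11 relatives (7 let-7 members, miR-98, miR-99a, miR-100 and miR-125b-5p) had a median log2 fold change of 0.28 (standard error 0.075), against -1.003 for the 3. That standard error came from resampling the 11 as if independent and leaves out error between arrays. Most of the 11 are relatives of let-7e. The relatives of miR-99b, miR-99a and miR-100, had 0.21 and -0.015, and that of miR-125a-5p, miR-125b-5p, had 0.54. Without db/+ replicates 1 and 4, miR-99b, let-7e and miR-125a-5p kept a mean share of 1.030. Their fall thus did not rest on these arrays alone, though they were chosen with both arrays included. A shared transcript stays a hypothesis: 29 other pairs of neighbours under 10 kb apart differed by a mean of 0.316, against 0.536 for shuffled pairs (one-sided permutation p = 0.0093), and p = 0.0307 when shuffled among neighbours alone, but p = 0.0853 over the 20 pairs outside one family and 17 of 29 pairs had the same sign. Whether neighbours in general move together thus stays open, and slide row and strain as such were not separable.

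miR-142-3p and miR-223 fell, by a mean of -0.92. A smaller share of leukocyte RNA in the db/db livers may account for this, but the other tested leukocyte miRNAs, miR-342-3p and miR-146a, had a median of -0.29 (standard error 0.19), between the bounds set for and against it, so it cannot be told apart from a change in those miRNAs alone; other leukocyte RNAs were not analysed here. Without db/+ replicates 1 and 4 the 2 kept a mean share of 1.090 (lowest 0.920), so their fall did not rest on these arrays alone. However, miR-223 lost its call there, and the 2 were chosen with these arrays included.

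A further hypothesis was that the 2 arms of a hairpin move together, as for miR-31 with miR-31* and for miR-378 with miR-378*, whose star strand did not pass limma's test. Across 9 other hairpins with 2 tested arms the arms differed by a mean of 0.503, against 0.554 for shuffled arms (one-sided permutation p = 0.269), and 4 of 9 had the same sign, so the arms of other hairpins gave no evidence for it.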
